A study of Mus musculus with 6 samples.

How the data were processed

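PolyA RNA of primary mouse melanocytes was measured in 6 libraries, 3 labelled BAP1 KO and 3 labelled WT. Per the labels' protocols, column-purified and DNase-treated total RNA went into a TruSeq RNA v2 preparation, which does not mark strand, and single-end reads of 50 bases were produced on a HiSeq4000. Per the submitters' processing notes, GSNAP and the GRCm38 genome build were used; the version of the aligner, the counting tool and the gene annotation are not given in the sources used here. Per the file headers, each file holds for every gene model the count of reads aligned uniquely to it, and a normalized RPKM, which is RPKM adjusted by a size factor. The deposited RPKM values differed from the counts by 1 factor per library and 1 per gene. The counts were used for every test, and the RPKM values only for the authors' library factors and for relative gene lengths.

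The files name 36528 gene models by numeric gene IDs. Of these, 31049 (85.0%) matched an entry of the RefSeq gene table of GRCm38.p6, 77 more took a symbol from GENCODE M21, and 5402 had none, with 1.05% of the reads. Coordinates are those of the RefSeq table on GRCm38. Libraries held 33987690 to 43773769 reads. Genes were kept by edgeR's filterByExpr with the group (minimum count 10, minimum total 15), which left 17121. Counts were scaled by TMM factors (0.975 to 1.03) and tested with edgeR 4.0.16 (glmQLFit without the robust option, glmQLFTest) in R 4.3.3, with no covariate, since the labels give no batch, date or pairing. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change over the square root of the F statistic, and levels are TMM-scaled CPM as mean ± SD of 3 libraries. The common biological coefficient of variation was 0.0536. Within each group every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 2.01 to 17.4 over genes with at least 20 reads in the pair), so no file repeats another. This does not show separate cultures or RNA samples, since preparations of 1 RNA can differ by as much.

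The test, the alternatives, 35 gene lists and the rule for naming genes were fixed before the data were examined. The rule names Bap1, Mitf, Bcl2, Mcl1 and Bcl2l1. It adds the 10 genes with the largest and the 10 with the smallest log2 fold change among called genes with an assigned symbol (no Gm, Rik, LOC or pseudogene name), at least 2 CPM in the higher group and no overlap between groups. It further adds up to 4 called members per list by absolute log2 fold change, and the 6 called genes with the highest mean CPM. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over all lists), with an estimated correlation, and with fry. Fry's test asks whether a list's genes move one way on balance and does not compare it with other genes. Annotated exon overlap on either strand and shared 50-base sequences were computed from GENCODE M21 with Python 3.11.15; genes with near-identical copies are reported as uncertain, and a share above 10%, a limit chosen after the data were examined, is given where a gene is named. Symbols absent from GENCODE M21 were matched to it by gene ID.

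Alternatives were DESeq2 size factors, library totals or upper-quartile factors in place of TMM, no count filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the robust option of edgeR, an adjusted p under 0.01, glmTreat against a log2 fold change of 1, and leaving out each library in turn. Scaling by the authors' own library factors and leaving out gene models without a symbol were added after the data were examined. The tests were tried on simulated data, negative binomial counts drawn from the mean levels, dispersions and library sizes of these files. Over 16788 simulated genes edgeR recovered 22% of 50 genes changed 1.2-fold, 68% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 11 false calls. Camera called the 1 planted list and 0 of 34 unchanged lists. Only 50 genes per fold were changed there and genes were drawn independently, whereas 81.5% of tested genes were called in the data. These rates therefore do not describe this comparison, scaling with most genes changed, or camera on correlated genes. Counts per exon and per transcript were not used here.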

Results

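Polyadenylated RNA was sequenced from primary melanocytes, the pigment-producing cells, of mouse skin. The series holds 6 libraries, 3 labelled BAP1 KO (knockout) and 3 labelled WT (wild type). BAP1 is a nuclear deubiquitinase that acts on histones and is lost in several tumour types, among them melanoma of the eye. As the study is known, the comparison asked whether loss of BAP1 changes the expression of the melanocyte regulator Mitf and of survival genes such as Bcl2 and Mcl1. The files gave uniquely aligned reads for 36528 gene models. Totals were 37934757, 43773769 and 36447473 reads in replicates 1, 2 and 3 labelled BAP1 KO, and 33987690, 37248641 and 40025282 reads in those labelled WT. Replicates were numbered by submission order and are not paired. No label says that they came from separate cultures or animals, so p-values measure only the spread between these libraries, which can be technical.

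Bap1, the targeted gene (gene ID 104416, chromosome 14, 31251352 to 31259930 on GRCm38, 17 merged exons), was read at 73.6, 77.3 and 72.5 CPM (counts scaled to library size) in the 3 libraries labelled BAP1 KO and at 55.7, 55.6 and 55.8 CPM in the 3 labelled WT. The level was therefore not lower under the knockout label. It was higher by 0.42 on the log2 scale (SE 0.042, edgeR adjusted p = 3.89e-06), a 1.34-fold difference. The counts pool all exons of the gene, so a deletion of some exons need not remove reads. Counts per exon were not used here. The targeted gene therefore did not mark the libraries labelled BAP1 KO, and every direction reported for this comparison rests on the labels alone. Higher and lower state the level in the libraries labelled BAP1 KO relative to those labelled WT, and differences are log2 fold changes unless a fold is named.

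Of the 6 called genes with the highest mean level, the pigment genes Tyrp1, Dct and Pmel and the mitochondrial transcript CYTB were higher in the libraries labelled BAP1 KO, and the matrix genes Fn1 and Thbs1 were lower. CYTB stood at 6068 ± 429 CPM in the libraries labelled BAP1 KO and 3800.0 ± 539 CPM in those labelled WT. Tyrp1, a melanin synthesis enzyme, stood at 32809 ± 530.2 CPM in the libraries labelled BAP1 KO and 2797 ± 7.38 CPM in those labelled WT (SD, n = 3 each). Thbs1, a secreted adhesion protein, stood at 508 ± 14.5 CPM in the libraries labelled BAP1 KO and 10608 ± 29.2 CPM in those labelled WT. By size of change, the 10 leading higher genes were Gng4 (a G protein gamma subunit), Frzb (a secreted Wnt antagonist), Fxyd7, Grin3a (a glutamate receptor subunit), Omg, Clec4n, S100b, Mrgprf, Abca8a and Gli1 (a Hedgehog pathway transcription factor). Their log2 differences ran from 6.86 for Gng4 down to 5.52 for Gli1. Gng4 rose from 0.276 ± 0.0986 to 33.2 ± 0.605 CPM (edgeR adjusted p = 2.39e-12), and Frzb from 1.51 ± 0.0706 to 114 ± 3.22 CPM. The 10 leading lower genes were Olr1 (a scavenger receptor), Plekhs1, Lcn2 (an iron-siderophore binding protein), Capsl, Ltf (lactoferrin), Tmprss11g, Ifi211, Tmem139, Ivl (involucrin of the cornified envelope) and Il3. They ran from -8.60 for Olr1 to -6.90 for Il3. Lcn2 was the most abundant of them, at 8.79 ± 0.336 CPM in the libraries labelled BAP1 KO and 1827 ± 115 CPM in those labelled WT (edgeR adjusted p = 5.91e-14). Ifi211 is uncertain, since 72.8% of its 50-base sequences are shared with other genes, Ifi205 most of all.

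Most expressed genes differed between the labels. Of 17121 genes tested, 6742 were higher and 7207 lower in the libraries labelled BAP1 KO, which was 81.5% of all tested. More than 2-fold differences were called for 2385 higher and 3883 lower genes, and more than 8-fold differences for 259 and 1520. The values of the 2 groups did not overlap for 82.7% of the tested genes, where chance gives 10%. The first principal component held 95.9% of the variance and parted the labels. Genes with at least 1 read numbered 21669 to 21927 in the libraries labelled BAP1 KO and 23421 to 23621 in those labelled WT. Against a log2 difference of 1 as the null, edgeR's glmTreat called 1818 higher and 3417 lower.

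Mitf and the pigment program were higher in the libraries labelled BAP1 KO, a direction that rests on labels the Bap1 counts did not bear out. Mitf, the master transcription factor of the melanocyte lineage (gene ID 17342, chromosome 6, 97807002 to 98021360 on GRCm38), stood at 262 ± 3.93 CPM in the libraries labelled BAP1 KO and 52.3 ± 5.66 CPM in those labelled WT (SD, n = 3 each), a 5.01-fold difference (log2 2.32 (SE 0.069), each library labelled BAP1 KO above each labelled WT, edgeR adjusted p = 1.28e-10). Of 34 pigment and lineage genes tested, 31 were higher and 3 lower, with a median log2 difference of 2.48. Plxnc1, a semaphorin receptor, had the largest at 4.34 (SE 0.047), followed by the melanosome protein Mlana at 3.78 (SE 0.067), the melanosomal transporter Oca2 at 3.57 (SE 0.036) and Tyrp1 at 3.55 (SE 0.029). Dct was 9.42-fold and Pmel 6.21-fold higher. The 3 lower members, named after their values were seen, were Gmpr (-1.50, 17.8% of its exons overlapping Atxn1), Slc7a11 (-0.64) and Trpm1 (-0.60). Camera, which tests whether a list ranks apart from the other genes, gave an adjusted p of 1.74e-32, and 0.0192 with an estimated correlation. In the same libraries the summed keratinocyte markers stood at 949 ± 25.03 CPM under the BAP1 KO label and 12121 ± 114 CPM under the WT label.

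**Figure D1:**
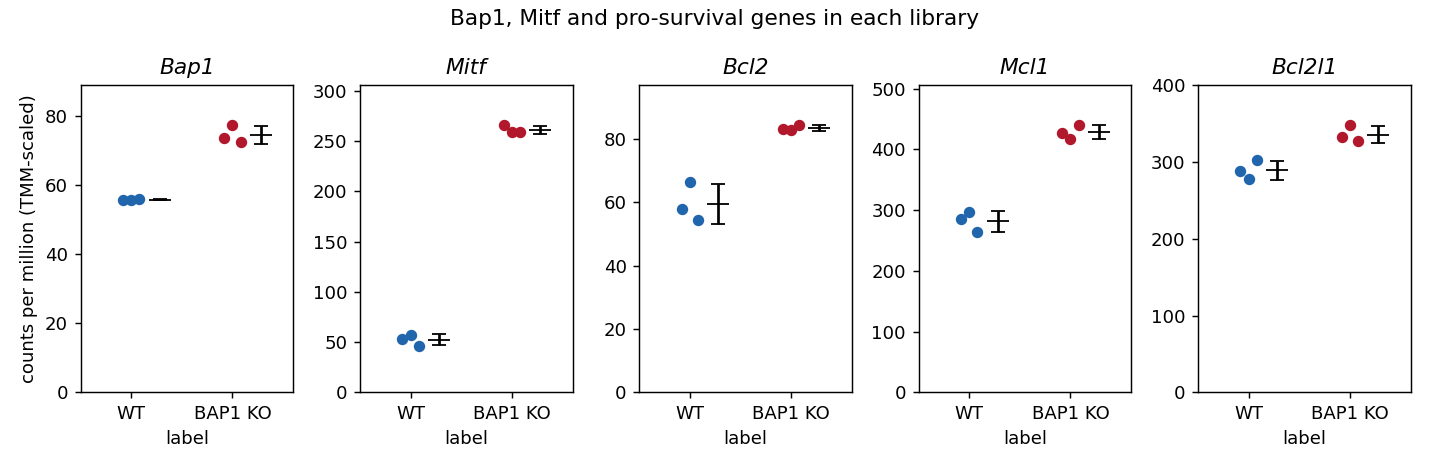
CPM (vertical axis, TMM-scaled, from 0) of Bap1, Mitf, Bcl2, Mcl1 and Bcl2l1 in each library by its label (horizontal axis), 3 libraries per label. Dots are libraries and bars the mean ± SD; Bap1 read 55.7 CPM on average under the WT label and 74.5 CPM under the BAP1 KO label.

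The survival genes differed less than Mitf, and all 4 pro-survival BCL-2 family genes tested were higher in the libraries labelled BAP1 KO, where the keratinocyte (median -4.01) and fibroblast (median -2.91) markers were lower. Bcl2 (gene ID 12043, chromosome 1, 106538176 to 106714290 on GRCm38) stood at 83.4 ± 0.901 CPM in the libraries labelled BAP1 KO and 59.5 ± 6.21 CPM in those labelled WT (SD, n = 3 each; log2 0.49 (SE 0.066), edgeR adjusted p = 4.39e-05). Mcl1 (gene ID 17210, chromosome 3, 95656944 to 95663179) stood at 428 ± 11.7 CPM in the libraries labelled BAP1 KO and 282 ± 17.1 CPM in those labelled WT (log2 0.60 (SE 0.047), edgeR adjusted p = 4.86e-07). Bcl2l1 (gene ID 12048, chromosome 2, 152758732 to 152833803), which encodes BCL-XL, differed by 0.21 (SE 0.043) (edgeR adjusted p = 8.04e-04). Bcl2l2, of which 12.1% is shared with Gm20521, was higher by 0.89 (SE 0.039). For Bcl2, Mcl1 and Bcl2l1 each library labelled BAP1 KO lay above each labelled WT. The list names 8 genes, of which Bcl2a1a, Bcl2a1b, Bcl2a1d and Bcl2l10 did not pass the count filter and were not tested. As a list the 4 genes tested had a median of 0.55 and did not rank apart from other genes (camera adjusted p = 0.264). Of 12 pro-apoptotic family members tested, 3 were higher, 6 lower and 3 not past the threshold; without WT replicate 2, 5 were higher. Pmaip1 (NOXA) fell 12.1-fold and Bid, with 18.8% of its exons overlapping Bcl2l13, 3.84-fold, and Bik and Bok were lower at -3.54 and -2.46; the list test gave camera adjusted p = 0.38. Among 23 death receptors, caspases and apoptosis inhibitors, 9 were higher and 13 lower, or 14 lower when adjusted over the list alone (camera adjusted p = 0.481). Ripk3 fell 7.60-fold, Tnfrsf10b 4.94-fold and Casp8 2.97-fold.

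Genes induced by p53 were lower as a group in the libraries labelled BAP1 KO. Of 32 tested, 27 were lower and 5 higher, with a median of -1.05 (camera adjusted p = 3.57e-06, and 0.0388 with an estimated correlation). Perp, a desmosome component that is also on the keratinocyte marker list, fell from 913 ± 92.3 to 30.6 ± 1.44 CPM. Plk2 fell 12.4-fold, Pmaip1 12.1-fold and Btg2 11.6-fold. Outside the naming rule and chosen after their values were seen, the p53 regulator Mdm2 fell from 621 to 192 CPM and the cell cycle inhibitor Cdkn1a from 946 to 380.0 CPM. Of the list, 8 genes are also on another list. The keratinocyte markers, at a median of -4.01, moved the same way in these libraries.

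Transcripts of other skin cell types were read in all 6 libraries, and those of keratinocytes and fibroblasts were far lower under the BAP1 KO label. All 27 keratinocyte markers tested were lower, with a median of -4.01 (camera adjusted p = 2.04e-35, and 0.0192 with an estimated correlation). Ivl was lower at -6.94 (SE 0.11) and the adhesion molecule Epcam at -5.55 (SE 0.040), from 1305 to 27.8 CPM, with Perp (-4.90) and Fermt1 (-4.57) next. The basal keratins Krt14 and Krt5, chosen after their values were seen as the usual abundant markers, stood at 96.5 and 68.0 CPM under the BAP1 KO label against 2001 and 1231 CPM under the WT label. Reads of Krt14 and Krt5 are uncertain to the extent that 13.9% and 8.52% of their 50-base sequences are shared with other keratins. Of 26 fibroblast markers, 24 were lower and 2 higher (median -2.91, camera adjusted p = 3.28e-08, and 0.0334 with an estimated correlation). Postn, a matrix protein, fell from 353 to 12.2 CPM and Fbln2 from 562 to 34.2 CPM. Col1a1 and Col1a2, the type I collagen chains, reached 64.9 and 9.33 CPM under the WT label and 3.64 and 0.584 CPM under the BAP1 KO label.

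Other cell type lists moved in both directions. Of 13 immune markers, 10 were higher and 3 lower (median 0.84, camera adjusted p = 0.205). Lyz2, a macrophage lysozyme gene of which 15.4% is shared with Lyz1, was 7.81-fold higher, Tyrobp and Cd68 were higher by 1.69 and 1.54, and Cd14 was lower at -4.32. Of 14 endothelial, mural and muscle markers, 10 were lower and 4 higher (median -1.54, camera adjusted p = 0.205), with Myh3 and Des under 3 CPM in every library and Cnn1 at 10.9 CPM under the WT label against 1.21 CPM. Among 17 Schwann cell and glial markers, 9 were higher and 7 lower (median 0.41, camera adjusted p = 0.366). S100b, a calcium-binding protein that melanocytes also make, rose 47.2-fold to 145 ± 8.72 CPM, whereas Ncmap and Fabp7 were lower at -3.56 and -3.18. Of 30 neural crest and dedifferentiation markers, 12 were higher and 18 lower (median -0.61, camera adjusted p = 0.27). Within it Nt5e fell 29.7-fold, Egfr 19.8-fold and the epithelial cadherin Cdh1 18.2-fold, from 2018 to 111 CPM. Sox2 was higher but stayed at 0.821 CPM, with 2 reads in all libraries labelled WT.

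**Figure D2:**
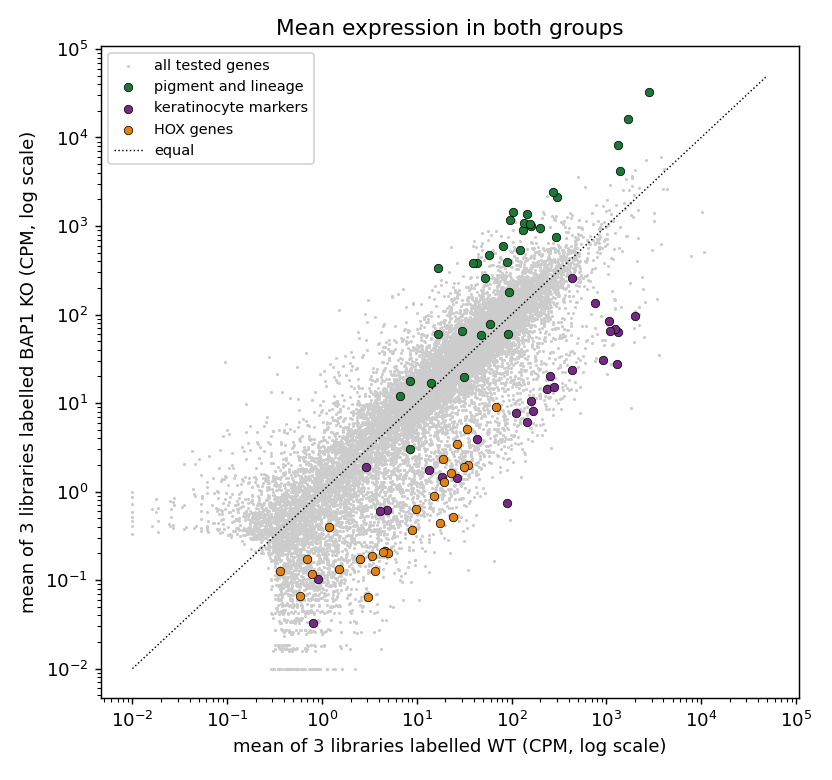
Mean CPM of each tested gene over the 3 libraries labelled WT (horizontal, log scale) and the 3 labelled BAP1 KO (vertical, log scale), with means under 0.01 CPM drawn at that value and no error bars. Pigment genes lie mostly above the line of equality and all keratinocyte markers and HOX genes below it; Tyrp1 is the topmost point at 32809 CPM.

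Genes under Polycomb control, which BAP1 opposes by removing ubiquitin from histone, were examined as groups. All 26 HOX genes tested were lower in the libraries labelled BAP1 KO, each by more than 2-fold, with a median of -3.94 (camera adjusted p = 6.48e-11; adjusted p = 0.101 with an estimated correlation). The largest differences were in the HOXA cluster on chromosome 6, at -5.58 (SE 0.34) for Hoxa6, -5.57 (SE 0.13) for Hoxa5, -5.32 (SE 0.16) for Hoxa7 and -4.77 (SE 0.25) for Hoxa4. Hoxa5 stood at 0.512 ± 0.163 CPM in the libraries labelled BAP1 KO and 24.0 ± 0.457 CPM in those labelled WT. Hoxa7 and Hoxa4 are uncertain because 20.4% and 16% of their exons overlap other transcripts. With at least 5 CPM required in 3 libraries, 13 HOX genes remained in the test and were lower. They are a subset of the 26 lower genes, so this adds no separate support. On average, 13 HOX genes reached 5 CPM under the WT label and 2 under the BAP1 KO label. Of 61 other developmental transcription factors, 18 were higher and 38 lower, or 39 lower when adjusted over the list alone (median -0.93, camera adjusted p = 0.354). With the same 5 CPM filter 8 of these factors were higher and 10 lower. Msx2 was lower at -4.35 (SE 0.10) and Gata3 at -4.07 (SE 0.14); Foxa2 was under 1 CPM in every library. Of 42 germline genes in the files, 10 passed the count filter and were tested. Of these 10, 2 were higher and 4 lower (median -0.30, camera adjusted p = 0.843), and 4 were higher without WT replicate 2. Without a count filter 4 germline genes were higher and 7 lower, and with the 5 CPM filter 1 was higher and 0 lower. Tdrd1 had 0 reads over the libraries labelled BAP1 KO and 55 over those labelled WT, at least 18.7-fold lower against a floor of 3 reads over the group, which covers counting error only; with it at that bound the list's median was -0.30. Keratinocyte markers fell together with the HOX genes (medians of -4.01 and -3.94).

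Subunits of Polycomb repressive complex 2 tended upward in the libraries labelled BAP1 KO, where the S and G2/M phase genes were also higher (median 0.81) and the keratinocyte (median -4.01) and fibroblast (median -2.91) markers lower. Of 12 tested, 9 were higher and 3 not past the threshold (median 0.68, camera adjusted p = 0.0173; adjusted p = 0.254 with an estimated correlation). With at least 5 CPM required in 3 libraries the camera adjusted p was 0.0528, within a range of 0.00293 to 0.0528 over the alternatives with the preset correlation. Jarid2 was 3.13-fold higher, the methyltransferase Ezh1 2.60-fold, Phf19 2.41-fold and Rbbp7 1.88-fold. Complex 1 subunits went both ways, 12 of 23 higher and 7 lower (median 0.17, camera adjusted p = 0.383), with Cbx7 (1.44) and Phc3 (1.26) higher and Pcgf3 lower (-0.83). Among 14 genes for proteins reported to bind BAP1, 9 were higher and 5 lower (median 0.57, camera adjusted p = 0.0895). Brca1, a DNA repair gene, was 3.52-fold, Mbd6 2.27-fold and the glycosyltransferase Ogt 2.25-fold higher, and Asxl3 fell from 4.50 to 2.23 CPM. This list passed the camera threshold without a count filter (adjusted p = 0.0220) and without WT replicate 3 (adjusted p = 0.0469). The range was 0.022 to 0.147 over the alternatives with the preset correlation, and the camera adjusted p with an estimated correlation was 0.254.

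**Figure D3:**
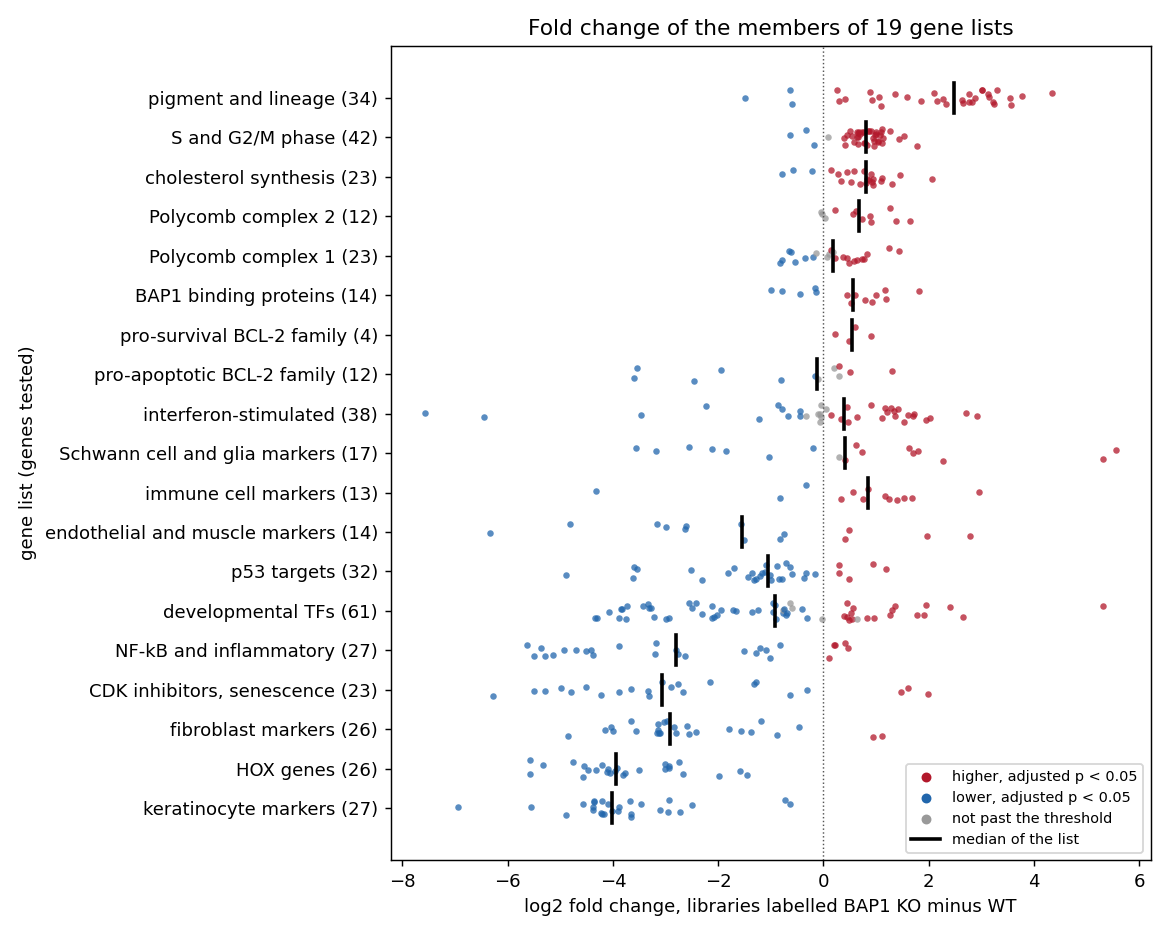
Log2 fold change of libraries labelled BAP1 KO minus WT (horizontal axis) for each tested member of 19 gene lists (vertical axis, genes tested in brackets), where a dot is a gene, its colour the edgeR call, and the bar the median of the list. Medians run from -4.01 for keratinocyte markers to 2.48 for pigment and lineage genes; Oas3, the lowest interferon point, had no reads under the BAP1 KO label, so its fitted value is no bound.

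S and G2/M phase genes were mostly higher, and the list of CDK inhibitors and senescence genes mostly lower, in the libraries labelled BAP1 KO. Of 42 S and G2/M phase genes, 38 were higher and 3 lower, with a median of 0.81 (camera adjusted p = 1.73e-05, and 0.0388 with an estimated correlation). Cenpf rose 3.44-fold, the proliferation marker Mki67 2.89-fold, Ccnb2 2.71-fold and Nusap1 2.39-fold; Mki67 stood at 208 ± 2.90 CPM in the libraries labelled BAP1 KO and 72.1 ± 2.93 CPM in those labelled WT. Of 23 CDK inhibitors and genes raised in senescent cells, 20 were lower and 3 higher (median -3.06, camera adjusted p = 3.18e-13, and 0.0387 with an estimated correlation). Cdkn2b (p15) fell from 182 ± 6.90 to 5.70 ± 0.372 CPM, and its neighbour Cdkn2a, chosen after its values were seen, from 116 ± 5.93 to 4.14 ± 0.224 CPM. The Cdkn2a count pools the transcripts of p16 and p19ARF. Tnfrsf11b, a decoy receptor, was lower at -6.28 (SE 0.11), and the chemokines Cxcl1 and Cxcl5 at -5.50 and -5.29. The 3 higher members, chosen after their values were seen, were the inhibitors Cdkn1b (1.99), Cdkn2c (1.61) and Cdkn2d (1.47). The CDK inhibitors on the list thus went both ways. Of the list, 8 genes are also on another list, Cxcl1 and Cxcl5 among them. Under the BAP1 KO label the keratinocyte markers together made up 949 ± 25.03 CPM, and under the WT label 12121 ± 114 CPM.

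Inflammatory genes were lower in the libraries labelled BAP1 KO, while interferon-stimulated genes moved both ways. Of 27 NF-kappaB targets and inflammatory genes, 22 were lower and 5 higher (median -2.79, camera adjusted p = 5.60e-12, and 0.0469 with an estimated correlation). The cytokine Tnf was lower at -5.64 (SE 0.11), and the chemokine Cxcl1 fell from 223 to 4.90 CPM. Ccl20 and Cxcl5 fell 41.0-fold and 39.2-fold. Of the list, 6 genes are also on another list, and the keratinocyte markers again moved with it (median -4.01). Of 38 interferon-stimulated genes, 21 were higher, 10 lower and 7 not past the threshold (median 0.39, camera adjusted p = 0.0675). Without a count filter the camera adjusted p was 0.0210, within a range of 0.021 to 0.147 over the alternatives with the preset correlation. With an estimated correlation the camera adjusted p was 0.254. Ifit3b, uncertain since 45% of it is shared with other genes and chiefly Ifit3, was higher by 2.91 (SE 0.12). Ifi44 was lower at -6.45 (SE 0.31). Oas3 had 0 reads under the BAP1 KO label and 70 under the WT label, at least 23.7-fold lower against the same floor, and the list's median with it at that bound was 0.39. Of 19 antigen presentation genes, 8 were higher and 9 lower (camera adjusted p = 0.585); the median was 0.067, the mean -0.34 and the test direction up, so they differed in sign. Psmb9, an immunoproteasome subunit with 11.7% of its exons overlapping Tap1, was 4.68-fold higher, and the class II gene H2-Ab1 was lower at -3.52.

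Matrix genes and the output genes of growth factor pathways were mostly lower in the libraries labelled BAP1 KO, as were the keratinocyte (median -4.01) and fibroblast (median -2.91) markers. Of 35 matrix, protease and adhesion genes, 24 were lower and 9 higher (median -0.73, camera adjusted p = 3.64e-06; adjusted p = 0.104 with an estimated correlation). The gelatinase Mmp9 fell 48.5-fold, Tnc 22.8-fold, from 3398 to 149 CPM, and Thbs1 20.9-fold. Fn1, on the fibroblast list, fell from 10320.2 ± 337 to 1433 ± 66.5 CPM. Of 18 MAPK output genes, 13 were lower and 4 higher (median -1.72, camera adjusted p = 2.06e-04; adjusted p = 0.104 with an estimated correlation). Etv4 was lower at -3.85 (SE 0.089) and Ier3 fell from 604 to 49.7 CPM. The cyclin gene Ccnd1 fell 10.3-fold, although 29.4% of its exons overlap a neighbouring gene. Of 25 TGF-beta and BMP pathway genes, 18 were lower and 4 higher (median -1.75, camera adjusted p = 2.25e-07; adjusted p = 0.0696 with an estimated correlation). Ccn2 fell from 2498 to 55.0 CPM, with 23.2% of its exons overlapped by another transcript. Inhba fell 38.8-fold, and the inhibitor of differentiation Id2 rose 14.3-fold to 384 CPM. Of 17 Wnt pathway genes, 5 were higher and 11 lower (median -0.99, camera adjusted p = 0.484). More than 2-fold differences were called for 3 higher and 8 lower members. The summed level of the list went the other way, at 6814 CPM under the BAP1 KO label against 2789 CPM under the WT label. Rnf43 was lower at -5.57 (SE 0.15), and the ligands Wnt10a and Wnt10b at -3.67 and -3.54.

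Cholesterol synthesis and lysosomal genes were mostly higher in the libraries labelled BAP1 KO, where 10 of 13 immune markers were also higher and the keratinocyte (median -4.01) and fibroblast (median -2.91) markers lower. Of 23 cholesterol genes, 20 were higher and 3 lower (median 0.81, camera adjusted p = 0.00128; adjusted p = 0.0721 with an estimated correlation). Insig1, a sterol sensor, was 4.19-fold higher, and the synthesis enzymes Lss and Mvk were 2.75-fold and 2.47-fold higher. Of 32 lysosome and autophagy genes, 24 were higher and 5 lower (median 0.48, camera adjusted p = 0.00467; adjusted p = 0.254 with an estimated correlation). Tfeb, a regulator of lysosomal genes, rose 3.86-fold and the cathepsin Ctss 4.91-fold. Of 27 oxidative phosphorylation genes, 16 were higher and 8 lower (median 0.19, camera adjusted p = 0.436). The coactivator Ppargc1b was higher by 2.48 (SE 0.076), and its relative Ppargc1a, which MITF is known to regulate, was lower at -1.47 (SE 0.055). Glycolysis and hypoxia genes divided evenly, 12 of 27 higher and 12 lower (camera adjusted p = 0.383), with a median of -0.032 against a mean of 0.00399 and an upward test direction. P4ha2, a collagen hydroxylase, was lower at -3.99 (SE 0.055), and Aldoc and Eno2 were higher by 3.07 and 2.96. Of 29 ATF4 and unfolded protein response genes, 15 were higher and 11 lower (camera adjusted p = 0.533), with a median of 0.18 and an upward test direction but a mean of -0.026. Nupr1 fell 12.5-fold, Ddit4 fell 5.49-fold and the amino acid transporter Slc7a5 rose 3.18-fold to 1126 CPM.

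The lists of ribosomal protein, mitochondrial, histone and sex-linked genes did not pass the camera threshold, apart from the ribosomal and mitochondrial lists with limma-voom. Of 40 ribosomal protein genes, 34 were lower and 6 not past the threshold (median -0.49, camera adjusted p = 0.205). With limma-voom the camera adjusted p was 1.34e-04, within a range of 1.34e-04 to 0.236 over the alternatives with the preset correlation. With an estimated correlation the camera adjusted p was 0.583. Their counts are uncertain, since ribosomal genes share sequence with many pseudogenes and reads were counted only where they aligned uniquely: Rpl27, with 23.5% of its 50-base sequences shared, was read at 1.97 CPM under the WT label and 0.847 CPM under the BAP1 KO label. Of 8 mitochondrially encoded transcripts, 6 were higher and 2 not past the threshold (median 0.81, camera adjusted p = 0.27). With limma-voom the camera adjusted p was 0.0415, within a range of 0.0415 to 0.38 over the alternatives with the preset correlation. With an estimated correlation the camera adjusted p was 0.648. COX1, a respiratory chain subunit, is uncertain because 51.1% of its 50-base sequences are shared with other genes, Gm29216 most of all; it stood at 4278 ± 279 CPM in the libraries labelled BAP1 KO and 2024 ± 481 CPM in those labelled WT. The list took 1.85% to 2.08% of the reads in the libraries labelled BAP1 KO and 0.920% to 1.36% in those labelled WT. The 10 most abundant genes took 8.56% to 8.84% and 5.59% to 5.74%. Of 12 replication-dependent histone genes, 4 were higher and 5 lower (camera adjusted p = 0.681). Their median was 1.07e-04 and turned sign between scalings, the mean was -0.55, and the test direction was up. H2bc21 was 8.87-fold higher, and H3c2 was lower at -4.50 but is uncertain, since 60.4% of its 50-base sequences are shared with other genes. Xist, which is made from the inactive X chromosome and overlaps Tsix over 11% of its exons, was read at 404 and 280.0 CPM under the BAP1 KO and WT labels, and the Y-linked gene Ddx3y at 68.7 and 33.3 CPM. Both were read in all 6 libraries, and 4 of the 5 sex-linked genes tested were higher (median 0.60, camera adjusted p = 0.38).

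Over all 35 lists, camera with the preset correlation called 14, 5 upward and 9 downward. With a correlation estimated per list, 7 of these held: pigment and lineage, S and G2/M phase, p53 targets, CDK inhibitors and senescence, NF-kappaB and inflammatory, fibroblast and keratinocyte genes. Counts of higher and lower members adjusted over the list alone equalled those over all genes tested, except for the death receptor list and the developmental transcription factors, for which both are given.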

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

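Scaling by the authors' library factors and leaving out gene models without a symbol were chosen after the data were seen; all other alternatives were planned. Bap1, Mitf, Bcl2 and Mcl1 kept their direction and their call under every alternative to the gene test except glmTreat, where single genes were not read. Their log2 differences were 0.34 to 0.46, 2.25 to 2.41, 0.41 to 0.58 and 0.53 to 0.65. GlmTreat was read as totals only. Bap1, Bcl2 and Mcl1 lie below the log2 difference of 1 that it tests against, and Mitf lies above it. Against 6742 higher and 7207 lower genes, leaving out 1 library gave 6506 to 7117 and 6915 to 7260, and DESeq2 gave 6518 and 6812; 13273 of the 13949 calls were also made by DESeq2 with the same sign. GlmTreat against a log2 fold change of 1 called 1818 higher and 3417 lower, since it asks for a larger difference. Among more than 2-fold calls (2385 higher and 3883 lower), the filter of 5 CPM in 3 libraries left 1446 and 2136, with 11930 genes tested in place of 17121; genes it removed have no value there. Leaving out 1 library gave 2440 to 2588 and 3944 to 4114 such calls, and 14 to 15 lists. Of 35 lists, 14 were called with the preset correlation, 7 with an estimated one, which allows for genes of a list moving together, and 35 with fry, which does not compare a list with other genes. The 4 other scalings moved the median log2 difference of all genes from -0.028 to between -0.090 (library totals) and 0.00179 (authors' factors), and higher genes made up 45.2% to 49.9% of the calls. Over the alternatives in scaling, filter, test tool and libraries, 4105 values of single genes and lists were compared. Of these, 4082 were unchanged, 3 lost a call, 5 gained one and 15 list counts moved by over 1.5 times. They do not cover the adjusted p under 0.01, glmTreat, the estimated correlation or fry. The estimated correlation and fry changed more list calls, as given above. Unchanged means the same direction and side of the threshold for a gene, and a count within 1.5 times for list members. For a list test it means the same side of the threshold, with direction compared only for called lists. Depth and replicate number can limit small differences and genes with few reads, which was not tested here. The simulation varied only the planted fold, and recovered the fewest of the smallest changes.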

Other observations

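The groups in this and the next paragraph, and the tests on dilution, on a lower melanocyte share, on keratinocyte-like cells and on exchanged labels, were chosen only after the results were seen; the length test and the counts of splits were set before. Of 11 Hedgehog pathway genes tested, 6 were higher and 3 lower in the libraries labelled BAP1 KO. Keratinocyte (median -4.01) and fibroblast (median -2.91) markers were lower in these libraries. Gli1, itself a target of the pathway, rose from 0.290 ± 0.0675 to 13.5 ± 0.0710 CPM, the receptor and target Ptch1 from 35.1 to 71.3 CPM, and the co-receptors Boc, Cdon and Gas1 by 2.05, 1.36 and 2.42 on the log2 scale, with 19.9% of the exons of Gas1 overlapping Gm48488. Smo, the signal transducer, and Sufu, an inhibitor, stood at -0.082 and 0.057 and did not pass the threshold, and Hhip (-0.76) and Gli3 (-0.20) were among the lower members. Of 21 genes tested for glutamate receptors, voltage-gated channels, the synaptic adhesion protein Lrrtm2 and the ion pump regulator Fxyd7, 12 were higher and 7 lower. The kainate receptor gene Grik3 rose from 2.84 to 103 CPM, the potassium channel genes Kcna1 and Kcna2 from 7.16 and 16.8 to 194 and 179 CPM, and the sodium channel gene Scn8a from 3.62 to 94.6 CPM, while Kcna4 and Kcna5 were lower at -4.25 and -3.60. Glutamate receptor genes also fell: the kainate receptor gene Grik1 stood at -4.48, from 1.22 to 0.0495 CPM, Gria3 at -1.02 and Grin1, with 13.5% of its exons overlapping Grin1os, at -0.95.

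All 15 genes tested of an epithelial defence list, made of antimicrobial and acute phase genes and the epithelial transcription factor Elf3, were lower in the libraries labelled BAP1 KO, with a median of -4.29, as were all 27 keratinocyte markers tested (median -4.01). Lcn2 stood at 1827 CPM under the WT label, Slpi, a protease inhibitor, at 233 CPM, Wfdc2 at 139 CPM and Ltf at 95.9 CPM, against 8.79, 9.24, 2.21 and 0.472 CPM. The calgranulin genes S100a8 and S100a9 were lower at -5.11 and -5.58, and Elf3 at -4.29. The list was made because several of its genes led the lower genes.

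Pigment genes were lower and keratinocyte markers higher in the libraries labelled WT. Dilution of identical melanocytes by other cells would give pigment-cell-restricted genes 1 common fold, but their log2 differences spanned 4.38 over 13 genes and 1.91 over the 11 left without Trpm1 and Foxd3, with no SE above 0.0666, which argues against dilution as the whole cause. A plain loss of melanocyte share would raise every other cell type alike, but the medians of 4 other cell type lists lay 4.86 apart. They were -4.01 for keratinocyte, -2.91 for fibroblast, -1.54 for endothelial or muscle and 0.84 for immune markers. The immune list sets the upper end and is thinly read: of 13 tested, 4 reached 5 CPM under the BAP1 KO label and 5 under the WT label. The other lists moved the same way. Outgrowth of 1 other cell type would not raise all alike, so this result does not speak to it. More keratinocyte-like cells under the WT label were not put to a test that could have failed: 20 of the 20 markers that reached 20 CPM there (100%) were higher there, among them Krt14 at 2001, Epcam at 1305 and Krt5 at 1231 CPM, but this follows from all 27 tested being lower under the BAP1 KO label, where 17 of them still reached 5 CPM. Such cells and an effect of the genotype on cell identity or on which cells grew out cannot be told apart, since label and culture coincide and the labels name no sort or gate.

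Bap1 reads were not lower under the BAP1 KO label, where the difference was 0.42 on the log2 scale. Exchanged labels predicted Bap1 more than 2-fold lower under the WT label, and it was 1.34-fold lower there. A deletion that leaves most exons transcribed need not lower the pooled count under either labelling, so exchanged and correct labels cannot be told apart from counts that pool the exons. If the labels were exchanged, each direction given here would turn, Mitf included.

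Ribosomal protein genes were lower under the BAP1 KO label, with a median of -0.49. A gene length trend was tested as an explanation. The median difference of all genes rose from -0.10 in the shortest of 5 length classes to 0.14 in the longest, both smaller in size than the ribosomal median. Once a loess on length was taken out the ribosomal median was -0.084 (bootstrap SE 0.067). The loess also takes out the mean level of genes, which the excess of over 8-fold lower genes (1520 against 259 higher) pulls down. This shift can come in part from that level, so the test cannot decide on length. Across genes, which are not independent, length and log2 difference had a Spearman correlation of 0.0697. Ribosomal protein genes are short themselves, so the loess may take out part of their own difference. What made the trend was not tested, and a biological difference in ribosomal transcripts stays open.

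The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. As many genes in 1 direction as the 6742 higher or the 7207 lower were called in 1 of the 10 splits, the real one; edgeR called 0 genes in each of the others, where 9 to 24 genes had an unadjusted p under 0.05. As many lists as the 14 called by camera with the preset correlation were called in 7 of the 10 splits, with up to 18 in another split. Every other split puts 2 libraries of 1 label with 1 of the other on each side, so the difference between labels remains in part in their list ranks. That difference also widens the spread within each side, so few or no gene calls were bound to follow there. The contrast in gene calls therefore says nothing about the real split. With an estimated correlation the real split called 7 lists and the others 0, a count on which the same mixing bears.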
